A study of Homo sapiens with 8 samples.

How the data were processed

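RNA sequencing counts were analysed for 8 libraries of HEK293F cells: 2 with MOV10 knockdown, 3 with MOV10 overexpression and 3 with an irrelevant siRNA as control. Per the labels' protocols, RNA was extracted with Trizol and stranded libraries were prepared from total RNA with a TruSeq kit. The deposited values are counts of reads per gene symbol, not normalized, made by the authors before deposition. Per the submitters' processing notes, CASAVA 1.8.2, Trimmomatic 0.22, TopHat2 2.0.8, HTSeq 0.5.3p9, SAMtools 0.1.18 and edgeR were used with the genome build hg19. The strand setting and the treatment of reads with several alignments are not given in the sources used here. Each library was assigned to its group and replicate number from its title, and each column of the count table was matched to the library of that title.

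The table held 23368 symbols, of which 3620 had no read. Symbols were matched to GENCODE 29 (20164 by gene name and 1457 by an older symbol, 1747 unmatched) for gene length, GC content and 3' UTRs of at least 50 nt. This annotation belongs to another genome build than the counts, so no coordinates are printed. After edgeR's filterByExpr with its defaults (a minimum count of 10 and a minimum total of 15), 15254 genes were tested. Total counts ran from 12.7 M to 32.8 M reads per library, a ratio of 2.58, and TMM factors from 0.961 to 1.03. The 10 most abundant genes took 2.37% to 2.52% of the counts of a library. The common biological coefficient of variation was 4.49%. Replicates were compared by a chi-square per gene, which lay between 1.85 and 7.81 for pairs of libraries of a group, so no pair agreed within sampling noise and each library was counted as a separate replicate.

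Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using TMM factors, glmQLFit and the quasi-likelihood F test, two-sided, in a single fit of all 8 libraries with a mean per group. P-values were adjusted by Benjamini-Hochberg, and genes under 0.05 were called. The contrasts were overexpression against control, knockdown against control, overexpression against knockdown, and the mean of both treatments against control. Log2 fold changes are given with their standard errors from this fit, and CPM values use TMM-scaled library sizes. On simulated counts with 200 changed genes and the means and depths of these libraries, edgeR recovered 43.3%, 77.6% and 90.9% of changes of 1.2, 1.5 and 2-fold with overexpression, and 32.8%, 79.1% and 86.4% with knockdown. False calls numbered 8 and 13 of 15254 genes. Far more genes were called in the real data, where the adjustment sets a less strict threshold. Neither the recovery nor the number of false calls therefore carries over to the real data.

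Fixed before the data were examined were 32 gene lists, the microRNA families, the comparisons, their tests and the rule for named genes. Lists with at least 3 measured members, 30 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists and both comparisons with control. In the direct contrast lists were adjusted within that contrast. At an estimated correlation 0 of the lists passed, and by fry 21 passed with overexpression and 14 with knockdown. Seed sites were 8-base matches in the longest annotated 3' UTR of 13637 genes, tested with camera for 12 families, 3 families not expected in kidney cells and reversed sequences. The genes named are MOV10, the 8 higher and 8 lower genes of each comparison with the largest absolute log2 fold change among called genes with a mean log2 CPM of at least 3 whose treated libraries all lay beyond every control library, up to 4 members of each list with the smallest adjusted p, and 5 genes of each kind for the relation of both responses. Some genes that this rule names are not reported here.

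The relation of the responses was set beside 50 simulated data sets in which no group differed and beside comparisons with separate control libraries. Alternatives were size factors, library totals, leaving MOV10 out of the counts, other count filters, DESeq2 1.42.0, limma-voom, only the compared groups in the fit, a fold threshold of 1.2, an adjusted p of 0.01, the replicate number as a block, offsets for GC content and length (mgcv 1.9.3), thinning to the shallowest library, fry and an estimated correlation for lists, other seed definitions, and leaving out each library. A scan of all 7-base words in 3' UTRs was added after the data had been examined. It was adjusted for 3' UTR length and base composition, covered genes with a mean log2 CPM of at least 2 and used 100 permutations of the genes. In its simulated test 10 of 10 planted words ranked first. The leading word and site were also chosen on a random part of the genes and measured on the rest, with equal parts and both ways. Other splits of the overexpression and control libraries were compared by the number of genes, lists and families they passed, and after an initial run the adjustment of lists in them was changed to 1 comparison. Mitochondrially encoded genes and 1 marker list with fewer than 3 measured genes were not analysed here as lists.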

Results

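RNA was sequenced from HEK293F cells, an established line derived from human embryonic kidney, in which the level of MOV10 had been changed. MOV10 is an RNA helicase that binds the fragile X protein FMRP and Argonaute proteins. It was lowered with siRNA in 2 libraries, raised with a plasmid for myc-tagged MOV10 in 3 libraries, and left alone in 3 control libraries from cells given an irrelevant siRNA. Counts summed to 32.8 M and 19.4 M in the knockdown libraries, to 23.4 M, 21.7 M and 12.7 M in the overexpression libraries, and to 22.7 M, 19.4 M and 15 M in the control libraries. No label says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The siRNAs were given 3 times at intervals of 24 h and the plasmid once, and no library with an empty plasmid was used here. The comparison of overexpression with control therefore holds the delivery of a plasmid and the irrelevant siRNA of the control cells, as well as the rise of MOV10.

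MOV10 itself moved as labelled in every library. It stood at 81.5 ± 8.44 CPM (counts scaled to a common library size) in control cells (SD, n = 3), at 53.1 ± 3.47 CPM with knockdown (n = 2) and at 2780 ± 284 CPM with overexpression (n = 3). The rise with overexpression was 34.2-fold, a log2 fold change of 5.10 ± 0.08 (SE) with an adjusted p of 2.1e-21 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With knockdown the mRNA fell by 0.62 on the log2 scale (SE 0.08, adjusted p = 8.84e-06 by the same test), which left 0.651 of the control level. MOV10 reads, those from the plasmid included, made up 0.251% to 0.304% of all counts in the overexpression libraries.

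**Figure D1:**
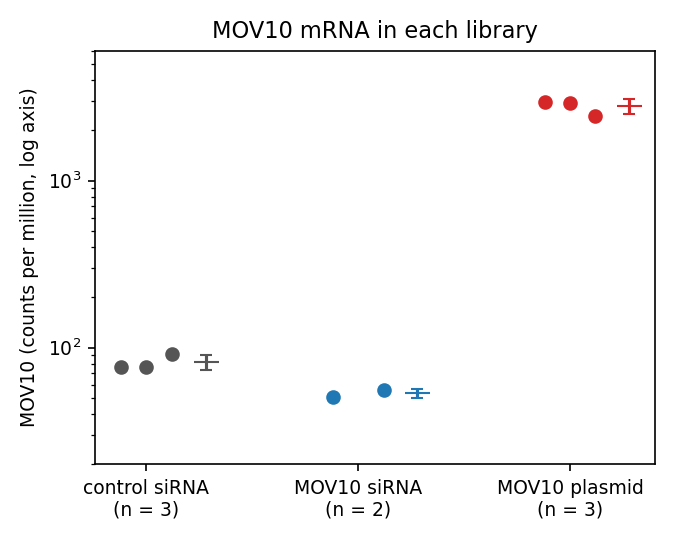
MOV10 mRNA in CPM on a log axis, with 1 point per library and the mean ± SD of each group beside its points. The overexpression libraries lie at 2454 to 2971 CPM, the control libraries at 76.4 to 91.2 CPM and the knockdown libraries at 50.6 and 55.5 CPM.

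The comparison of overexpression with control asked which transcripts change when MOV10 is abundant. HSPA6, a stress-inducible member of the HSP70 family, rose most among the genes named by size, from 0.281 ± 0.110 to 22.1 ± 2.70 CPM (SD, n = 3 each), a log2 fold change of 6.28 ± 0.19. Every control library held it at less than 1 CPM, so the size of this fold is imprecise. C1orf95 rose by 1.97 ± 0.09 (log2, SE, as for the fold changes that follow), LPPR3 by 1.84 ± 0.14, the collagen-binding receptor gene MRC2 by 1.62 ± 0.09 and NR1D1, which encodes a circadian repressor, by 1.61 ± 0.08. The linker histone genes H1F0 and HIST1H1C rose by 1.56 ± 0.05 and 1.54 ± 0.06, and HIST1H2BD by 1.55 ± 0.09. Lower transcripts included PRR22 (-1.32 ± 0.16), PKI55 (-1.10 ± 0.13), RAB36 (-0.98 ± 0.11), DRP2 (-0.96 ± 0.10), the amino acid transporter gene SLC43A2 (-0.95 ± 0.08), the protein kinase A regulatory subunit gene PRKAR1B (-0.94 ± 0.08), FOSB (-0.93 ± 0.09) and SCAMP5 (-0.92 ± 0.08). As the rule for named genes required, each of these genes lay beyond every control library in all 3 overexpression libraries. The highest of their edgeR adjusted p-values was 9.56e-07.

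Among 15254 genes tested, 3837 were higher and 3671 lower with overexpression (edgeR, adjusted p under 0.05). Most of these shifts were small, with a median absolute log2 fold change of 0.33 among the called genes, and 352 genes rose and 98 fell by at least 2-fold. Tested against a fold of 1.2, the counts were 1491 and 859. Scaling by library totals alone in place of TMM gave 4520 higher and 2997 lower, so the share of called genes that were higher was 60.1% against 51.1%.

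Histone genes and genes of the cell surface and its matrix rose together with overexpression. Of 40 measured replication-dependent histone genes, 26 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 0.96. The camera adjusted p was 3.96e-09, and the adjusted p = 0.382 with an estimated correlation. HIST2H2BE rose by 1.05 ± 0.09 and HIST1H4E by 1.93 ± 0.21. Histone genes are near-identical copies of one another, so the counts of single members are uncertain. Of 50 genes of the extracellular matrix and adhesion, 35 rose and 1 fell (35 and 3 adjusted over the list alone), with a median of 0.32, a camera adjusted p of 2.65e-11 and an adjusted p = 0.229 with an estimated correlation. Among them the laminin chain gene LAMC1 rose by 0.94 ± 0.05, the integrin gene ITGA5 by 0.80 ± 0.06, and the collagen genes COL5A1 and COL6A2 by 1.19 ± 0.09 and 1.08 ± 0.09. A separate list of fibroblast markers, many of them matrix genes, had 4 of 6 measured genes higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.73, a camera adjusted p of 0.126 and a fry adjusted p of 0.000959.

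Several stress responses also moved upward with overexpression. Of 38 genes of the amino acid response and ATF4 targets, 25 rose and 3 fell (25 and 4 adjusted over the list alone, median 0.27, camera adjusted p = 4.59e-07, adjusted p = 0.229 with an estimated correlation). They included ATF3 (0.73 ± 0.05), CTH (0.92 ± 0.07), a gene of cysteine synthesis, and SHMT2 (0.73 ± 0.06), a mitochondrial gene of serine and glycine metabolism. Of 24 heat shock and cytosolic chaperone genes, 13 rose and 6 fell (14 and 6 adjusted over the list alone, median 0.13, camera adjusted p = 1.17e-05, adjusted p = 0.229 with an estimated correlation). HSPA1A and HSPA1B, which share nearly all of their sequence and cannot be counted apart with certainty, rose by 0.90 ± 0.05 and 0.84 ± 0.05, DNAJB1 rose by 0.81 ± 0.05, and the constitutive HSPA8 fell by 0.40 (SE 0.04). In the list of endoplasmic reticulum stress genes, 10 of 22 rose and 1 fell (11 and 3 adjusted over the list alone, median 0.13, camera adjusted p = 0.0121, adjusted p = 0.389 with an estimated correlation), with HERPUD1 at 0.75 ± 0.05 and XBP1 at 0.62 ± 0.06. Among 26 p53 targets, 12 rose and 4 fell (12 and 4 adjusted over the list alone, median 0.12, camera adjusted p = 0.000958, adjusted p = 0.382 with an estimated correlation). The growth-arrest genes BTG2 and CDKN1A rose by 0.84 ± 0.05 and 0.83 ± 0.06. Immediate early genes moved both ways: 14 of 31 rose and 6 fell (17 and 6 adjusted over the list alone, median 0.32, camera adjusted p = 0.00514, adjusted p = 0.382 with an estimated correlation), with KLF10 at 1.25 ± 0.06 and JUN at 0.47 ± 0.04 against EGR1 at -0.91 ± 0.07.

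Zinc finger genes named ZNF, most of them transcription factors, were higher as a group, with 202 of 470 up and 62 down (208 and 65 adjusted over the list alone, median 0.15). The camera adjusted p was 0.000253, and the adjusted p = 0.382 with an estimated correlation. ZNF184 rose by 1.13 ± 0.06, ZNF256 by 1.02 ± 0.07 and ZNF467 by 1.40 ± 0.11. Host genes of small nucleolar RNAs were higher in 6 of 17 cases and lower in 0 (6 and 0 adjusted over the list alone, median 0.08, camera adjusted p = 0.0375, adjusted p = 0.485 with an estimated correlation), with SNHG15 at 0.75 ± 0.06 and GAS5 at 0.50 ± 0.06. That camera call was lost without control replicate 2 (adjusted p = 0.0652) or overexpression replicate 2 (0.0514).

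Proteasome genes, nonsense-mediated decay factors, proliferation genes, translation factors and splicing factors were lower with overexpression. Of 31 proteasome genes, 23 fell and 1 rose (23 and 2 adjusted over the list alone, median -0.19, camera adjusted p = 3.69e-05, adjusted p = 0.419 with an estimated correlation), with PSMD2 and PSMA7 both at -0.44 ± 0.05 and PSMD11 at -0.42 ± 0.05. Of 16 factors of nonsense-mediated decay, which degrades mRNAs with premature stop codons, 10 fell and 0 rose (10 and 0 adjusted over the list alone, median -0.17, camera adjusted p = 0.00134, adjusted p = 0.299 with an estimated correlation). RBM8A stood at -0.53 ± 0.05 and SMG6 at -0.51 ± 0.06. Proliferation genes fell in 22 of 45 cases and rose in 4 (22 and 4 adjusted over the list alone, median -0.12, camera adjusted p = 0.00936, adjusted p = 0.382 with an estimated correlation), led by the cell-cycle regulator FOXM1 (-0.70 ± 0.05) and the mitotic cyclin gene CCNB1 (-0.35 ± 0.04). Translation initiation and elongation factors fell in 18 of 35 cases and rose in 4 (19 and 4 adjusted over the list alone, median -0.14, camera adjusted p = 0.0185, adjusted p = 0.484 with an estimated correlation), including EIF5A (-0.45 ± 0.06) and EIF4G2 (-0.39 ± 0.04). Splicing factors fell in 14 of 33 cases and rose in 3 (15 and 3 adjusted over the list alone, median -0.09, camera adjusted p = 0.0419, adjusted p = 0.761 with an estimated correlation), with HNRNPM at -0.63 ± 0.05. Without control replicate 1 the camera adjusted p for splicing factors was 0.089, and without overexpression replicate 2 it was 0.172.

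The comparison of knockdown with control asked which transcripts change when MOV10 is reduced. DHRS2, a short-chain dehydrogenase gene, rose by 1.70 ± 0.10 with knockdown, and the smooth muscle actin gene ACTA2 by 1.64 ± 0.09. The histone genes HIST1H4H, HIST1H2AC and HIST1H2BD rose by 1.63 ± 0.13, 1.29 ± 0.14 and 1.26 ± 0.10, FOSB by 1.40 ± 0.08, SLC4A5 by 1.21 ± 0.12 and APLP2, a relative of the amyloid precursor protein gene, by 1.19 ± 0.05. The transcripts that fell included BSPRY (-1.91 ± 0.14), the fucosyltransferase gene FUT1 (-1.31 ± 0.13), the septin gene SEPT3 (-1.24 ± 0.09), PACSIN1 (-1.23 ± 0.15), CPT1C (-1.22 ± 0.12), EBF2 (-1.21 ± 0.10) and the spectrin gene SPTBN4 (-1.19 ± 0.12). In both knockdown libraries each of these genes lay beyond every control library, as the same rule required, and their highest edgeR adjusted p was 1.76e-06.

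With knockdown 3036 genes were higher and 2907 lower (edgeR, adjusted p under 0.05). Those changed by at least 2-fold numbered 155 higher and 307 lower. Tested against a fold of 1.2, the counts were 722 and 978. Scaling by library totals alone in place of TMM gave 2353 higher and 3611 lower, so the share of called genes that were higher was 39.5% against 51.1%. Without knockdown replicate 2 the counts were 1577 and 1466, with the lone remaining library assumed to vary like those of the other groups. Of the called lower genes with an annotated 3' UTR, 20.3% held at least 1 of the 8-base words AGCAAACA, GTCTGTTA and TGGGTCTT there, against 11.2% of all such genes and 6.64% of the higher ones. The words were chosen because genes holding them were lower in this comparison, so a higher share among the lower genes is favoured by the choice. How much of these shares the choice accounts for was not measured. SEPT3 holds such a word, and so do ATF3 and ZNF268, which rose with knockdown. A 7-base core, meaning the first or last 7 bases of such a word, occurred in 44.6% of all genes with an annotated 3' UTR. It occurred in 59.0% of the lower and 37.7% of the higher ones. Without the genes that hold a core, a choice made after the data had been examined, 1969 genes were higher and 1308 lower.

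Growth-arrest and early-response genes rose with knockdown. Of 26 p53 targets, 23 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.52, a camera adjusted p of 2.28e-13 and an adjusted p = 0.229 with an estimated correlation. CDKN1A, the inhibitor of cyclin-dependent kinases, rose by 1.16 ± 0.06, the death receptor gene TNFRSF10B by 0.68 ± 0.05, BTG2 by 0.60 ± 0.06 and GADD45A by 0.52 ± 0.05. Of 31 immediate early genes, 23 rose and 3 fell (23 and 3 adjusted over the list alone, median 0.44, camera adjusted p = 2.28e-12, adjusted p = 0.229 with an estimated correlation), among them KLF10 (0.98 ± 0.06), EGR1 (0.94 ± 0.07) and ATF3 (0.63 ± 0.05). Replication-dependent histone genes rose in 30 of 40 cases and fell in 0 (32 and 0 adjusted over the list alone, median 0.98, camera adjusted p = 1.33e-12, adjusted p = 0.331 with an estimated correlation). HIST1H2BK rose by 0.79 ± 0.07 and HIST1H1C by 0.76 ± 0.07.

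Matrix, chaperone and ribosomal genes were higher with knockdown as well. Of 50 genes of the extracellular matrix and adhesion, 27 rose and 7 fell (30 and 7 adjusted over the list alone, median 0.25, camera adjusted p = 4.59e-07, adjusted p = 0.331 with an estimated correlation), with LAMC1 at 1.17 ± 0.06, the basement membrane gene NID1 at 1.10 ± 0.05, the fibrillin gene FBN2 at 0.74 ± 0.07 and the integrin gene ITGB1 at 0.63 ± 0.06. Of 22 endoplasmic reticulum stress genes, 13 rose and 2 fell (14 and 3 adjusted over the list alone, median 0.20, camera adjusted p = 0.000104, adjusted p = 0.331 with an estimated correlation), including MANF (0.65 ± 0.06) and the chaperone genes HYOU1 (0.57 ± 0.06) and CALR (0.56 ± 0.05). Of 24 heat shock and cytosolic chaperone genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.14, camera adjusted p = 0.00549, adjusted p = 0.382 with an estimated correlation), with HSPA8 at 0.51 ± 0.05. Cytosolic ribosomal protein genes rose in 31 of 76 cases and fell in 2 (33 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.000122, adjusted p = 0.549 with an estimated correlation), including RPL9 (0.38 ± 0.06) and RPL24 (0.34 ± 0.05). Zinc finger genes named ZNF rose in 133 of 470 cases and fell in 44 (132 and 44 adjusted over the list alone, median 0.07, camera adjusted p = 0.0272, adjusted p = 0.549 with an estimated correlation), with ZNF268 at 0.76 ± 0.07 and ZNF117 at -1.03 ± 0.11. Factors of mRNA decapping, deadenylation and P-bodies rose in 13 of 33 cases and fell in 7 (13 and 7 adjusted over the list alone, median 0.08, camera adjusted p = 0.0358, adjusted p = 0.549 with an estimated correlation). ZFP36L1, which binds AU-rich elements, rose by 1.11 ± 0.06, while LSM14B and the deadenylase gene CNOT8, which holds an 8-base word named above, stood at -0.67 ± 0.06 and -0.58 ± 0.06. The decapping list lost its call without control replicate 3 (adjusted p = 0.066), without knockdown replicate 2 (0.116) and with the replicate number as a block (0.0555).

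Interferon-stimulated and neuronal genes were lower with knockdown. Of 37 interferon-stimulated genes, 16 fell and 0 rose (16 and 0 adjusted over the list alone, median -0.26, camera adjusted p = 0.0154, adjusted p = 0.229 with an estimated correlation). HERC5 stood at -0.51 ± 0.07, IFITM1 at -0.95 ± 0.19, IFI44L at -0.99 ± 0.21 and OAS3 at -0.46 ± 0.11, and IFITM1 and IFI44L were at less than 5 CPM in control. Of 39 genes of the neuronal cytoskeleton and projection, 16 fell and 8 rose (16 and 9 adjusted over the list alone, median -0.07, camera adjusted p = 0.0305, adjusted p = 0.382 with an estimated correlation). The axon guidance gene DPYSL2 stood at -0.81 ± 0.06 and the microtubule regulator gene STMN1 at -0.50 ± 0.05. DPYSL2 holds an 8-base word named above. The neuronal call was lost without genes holding a 7-base core (camera adjusted p = 0.414), which left 12 of the 39 genes. Since the words were chosen on genes lower in this comparison, that removal works against a lower list by construction. The neuronal call was also lost without knockdown replicate 2, which leaves 1 knockdown library.

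**Figure D2:**
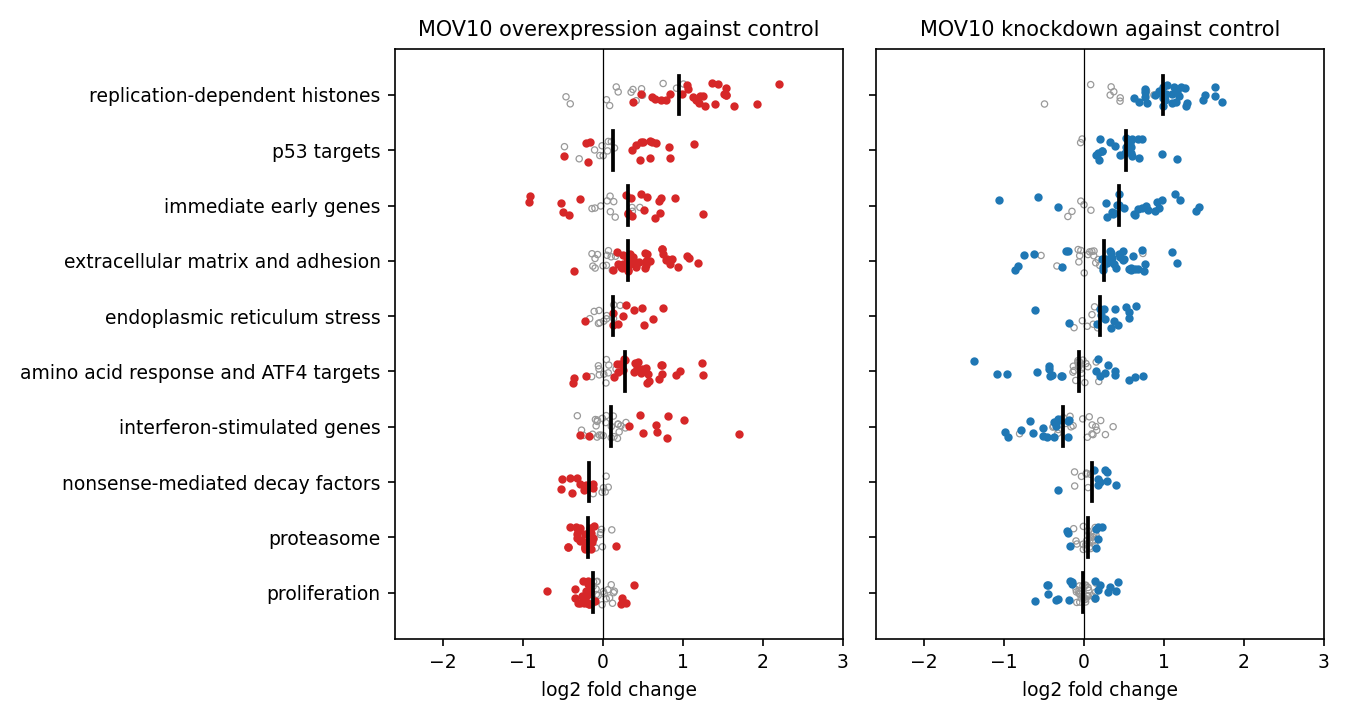
Log2 fold changes of single genes in 10 of the gene lists, for overexpression (left) and knockdown (right) against control. Each point is a gene, filled where the edgeR adjusted p was under 0.05, and the black bars are list medians. Histone genes lie to the right in both panels (medians 0.96 and 0.98), p53 targets have medians of 0.12 and 0.52, and proteasome genes have medians of -0.19 and 0.05.

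The series concerns microRNA-mediated regulation, and genes of that machinery and of its targets were therefore listed in advance. Of 21 genes of microRNA biogenesis and the silencing complex, 4 were higher and 7 lower with overexpression (4 and 7 adjusted over the list alone, camera adjusted p = 0.421). XPO5, the exporter of microRNA precursors, stood at -0.38 ± 0.04 and the RNA-editing gene ADAR at -0.24 ± 0.04. With knockdown 6 were higher and 3 lower (6 and 4 adjusted over the list alone, camera adjusted p = 0.344), with TNRC6A, a scaffold of the silencing complex, at 0.37 ± 0.06. Of 19 genes of the FMRP family and its partners, 4 were higher and 9 lower with overexpression and 4 higher and 7 lower with knockdown (the same counts adjusted over the list alone, camera adjusted p = 0.251 and 0.497). YBX1, an mRNA-binding protein gene, stood at -0.48 ± 0.05 with overexpression and 0.34 ± 0.06 with knockdown, and G3BP1, a stress granule gene that holds an 8-base word named above, at -0.60 ± 0.05 with knockdown. Of 22 known let-7 targets, 8 were higher and 8 lower with overexpression (8 and 8 adjusted over the list alone, camera adjusted p = 0.948), with CCND1 at 0.63 ± 0.05 and HMGA1 at -0.46 ± 0.06. With knockdown 0 were higher and 6 lower (0 and 6 adjusted over the list alone, camera adjusted p = 0.0623), with CCND2 at -0.79 ± 0.06 and HMGA2 at -0.32 ± 0.06. The let-7 list passed with knockdown when control replicate 3 (adjusted p = 0.0473) or overexpression replicate 3 (0.0286) was left out, and with offsets for GC content and length (0.0317), which were chosen after the data had been examined. By fry, which tests whether the genes of a list move one way on balance, its adjusted p with knockdown was 0.00335. Such a pass was common: fry passed 14 of 30 lists with knockdown and 21 with overexpression. The FMRP list was among those that passed with overexpression (fry adjusted p = 0.0304). CCND2 and HMGA2 hold a 7-base core of the words named above, as do 44.6% of all genes with an annotated 3' UTR. Without genes holding one, 2 of 10 let-7 targets were lower and 0 higher with knockdown (camera adjusted p = 0.168). Their median was -0.12, against -0.08 for the whole list.

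Genes with 8-base microRNA seed sites in the 3' UTR were compared with genes without them for 12 microRNA families. By camera 0 of the 12 families passed an adjusted p of 0.05 in either comparison. Shorter sites, the shortest 3' UTR of a gene and a matched background gave 0 families as well. At an unadjusted threshold of 0.05, camera would have passed 3 families with overexpression and 0 with knockdown. The lowest values were 0.0302 for miR-25/32/92 over 511 genes with overexpression (camera adjusted p = 0.482) and 0.319 with knockdown. The median log2 fold change of genes with a site exceeded that of genes without one by 0.0061 to 0.0705 in all 12 families with overexpression, and reversed site sequences gave a difference above 0 in 9 of 12 cases. For families not expected in kidney cells the differences were above 0 in 3 of 3 cases. With knockdown the differences ran from -0.0288 to 0.0103 and were above 0 in 3 of 12 families, in 1 of 12 reversed sequences and in 0 of 3 families not expected in kidney cells.

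The direct contrast of overexpression with knockdown tests where the responses differ. It called 4467 genes higher and 4289 lower with overexpression (edgeR, adjusted p under 0.05), and 2475 and 1522 when tested against a fold of 1.2. Scaling by library totals gave 5709 and 3001, which raised the share of higher genes from 51.0% to 65.5%, with a median of all genes of 0.10 on the log2 scale in place of 0.02. Relative to knockdown, proteasome genes (median -0.22, camera adjusted p = 0.000202, adjusted p = 0.556 with an estimated correlation) and nonsense-mediated decay factors (median -0.41, camera adjusted p = 0.000202, adjusted p = 0.333 with an estimated correlation) were lower with overexpression. The p53 targets were lower too (median -0.28, camera adjusted p = 0.0172, adjusted p = 0.572 with an estimated correlation). Genes of the amino acid response (median 0.23, camera adjusted p = 0.000225, adjusted p = 0.537 with an estimated correlation) and interferon-stimulated genes (median 0.33, camera adjusted p = 0.0172, adjusted p = 0.333 with an estimated correlation) were higher. Immediate early genes (median -0.14, adjusted p = 0.0172), splicing factors (-0.14, 0.0172), translation factors (-0.15, 0.0182), oxidative phosphorylation genes (-0.13, 0.0182) and ribosomal protein genes (-0.11, 0.0281) were lower by camera, and 0 of these lists passed with an estimated correlation. For histone genes the median difference was -0.04 (camera adjusted p = 0.716).

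Many genes moved the same way in both comparisons with control, and others in opposite ways. ZFP36L1, LAMC1, TMCO1, WDFY1 and the cartilage collagen gene COL2A1 rose in both comparisons, by 0.85 to 1.10 with overexpression and by 0.96 to 1.17 with knockdown. SEC61A2, KIF1C, FOXQ1, ZNF117 and IDS, the gene of the lysosomal enzyme iduronate sulfatase, fell in both, to between -0.51 and -0.91 and between -0.63 and -1.03. FUT1 (0.90 ± 0.09 and -1.31 ± 0.13), the surface glycoprotein gene CD24 (0.83 ± 0.08 and -0.79 ± 0.10), TCF24 (0.83 ± 0.11 and -1.12 ± 0.15), FAM8A1 (0.43 ± 0.06 and -0.56 ± 0.07) and PNMA2 (0.41 ± 0.06 and -0.54 ± 0.06) rose with overexpression and fell with knockdown. EGR1, FOSB, HSPA8, GADD45B (-0.59 ± 0.07 and 0.82 ± 0.07) and STAG1 (-0.39 ± 0.05 and 0.53 ± 0.06) did the reverse. The words described above occur as 8-base matches in IDS, KIF1C, FAM8A1 and TCF24.

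In both comparisons 1114 genes were called higher and 883 lower, against 764 and 699 from independent lists of these sizes. Another 551 were higher with overexpression and lower with knockdown, and 596 the reverse, against 731 and 731 from independent lists. Both comparisons share the control libraries, which independent lists leave out, so part of the excess of genes called the same way may come from the shared controls. In 50 simulated data sets without any change 0 genes were called in both by edgeR, a value that leaves out the effects of the treatments. On the mean of both treatments against control, which a change in only 1 of them can carry, 2819 genes were higher and 2892 lower (edgeR, adjusted p under 0.05), and 548 and 354 when tested against a fold of 1.2. By camera on this mean, histone genes (median 0.88, adjusted p = 1.23e-16), matrix and adhesion genes (0.24, 1.07e-14), p53 targets (0.29, 2.04e-12), immediate early genes (0.29, 3.69e-10), endoplasmic reticulum stress genes (0.21, 1.69e-05), heat shock genes (0.15, 1.91e-05), ZNF genes (0.10, 4.5e-05), amino acid response genes (0.08, 0.000986) and ribosomal protein genes (0.08, 0.0033) were higher. Proliferation genes (-0.07, 0.0304) and proteasome genes (-0.08, 0.0446) were lower, and with an estimated correlation the lowest adjusted p of these lists was 0.172. Proliferation, proteasome and amino acid response genes had medians of -0.01, 0.05 and -0.06 with knockdown and did not pass there, and ribosomal protein genes had a median of 0.04 with overexpression and did not pass there. Across 15253 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.150, a Spearman correlation of 0.119 and a covariance of 0.0246. The simulated data sets gave a mean Pearson correlation of 0.482, above the observed one, and a covariance of 0.0101. The observed covariance exceeded the simulated one by 0.0145. With separate control libraries for each comparison the Pearson correlation was 0.0441 to 0.145, against 0.162 by the same method with shared controls, and the covariance 0.00703 to 0.0211 against 0.0231. Each of those splits leaves 1 control library on one side.

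**Figure D3:**
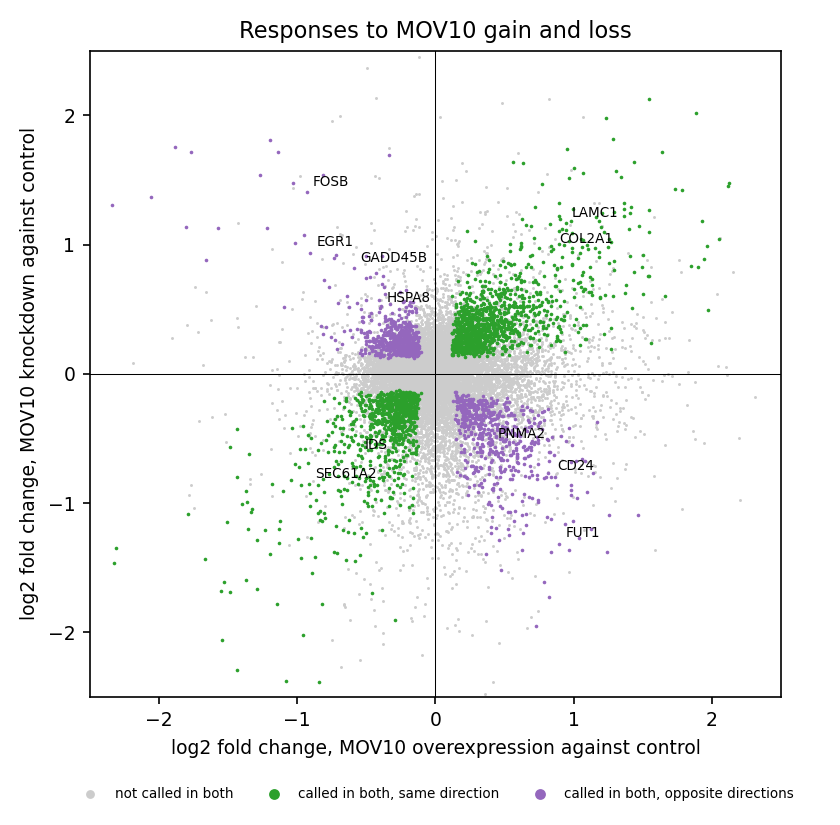
Log2 fold change of each gene with MOV10 overexpression (horizontal) and knockdown (vertical) against the same control libraries, with MOV10 left out and 26 genes outside the axes. Green points were called in both comparisons in the same direction (1114 higher, 883 lower) and purple points in opposite directions (551 and 596). FOSB and EGR1 lie at the upper left and FUT1 and CD24 at the lower right.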

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

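The offsets for GC content and length in list tests and the removal of genes with 3' UTR words were chosen after seeing the data. No named gene or list changed direction past its threshold: of 278 named gene results 75 lost or gained a call under some setting, and of 60 list results 37 did, with 0 reversed. With an estimated correlation 0 and 0 lists passed, in place of 14 with overexpression and 11 with knockdown. A threshold fold of 1.2 gave 1491 higher and 859 lower genes with overexpression, 722 and 978 with knockdown, 2475 and 1522 in the direct contrast, and 548 and 354 for the mean of both treatments. By construction it drops small changes. An adjusted p of 0.01 left 1912 genes lower with knockdown, and 1878 higher and 1865 lower for the mean. Without genes holding a 7-base core of the 3' UTR words 1969 were higher and 1308 lower with knockdown. Fewer genes were counted, and the removal took out 59.0% of the lower and 37.7% of the higher genes with an annotated 3' UTR. Choosing the words on genes lower in this comparison favours that imbalance. The choice need not be all of it. Among genes not used for the choice, those with AGCAAACA still lay lower than those with only its 6-base core. The differences were -0.137 ± 0.0216 and -0.114 ± 0.0238 (mean log2, SE) in 5778 and 5777 genes. The Pearson correlation of both responses was 0.0441 with control 1 kept for overexpression, 0.0802 with control 2 kept for knockdown and 0.0497 with control 3 kept for knockdown. With control 1 kept for knockdown it was 0.145, and with control 2 or 3 kept for overexpression 0.104 or 0.125. By the same method with shared controls it was 0.162, and the cause was not tested.

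Leaving out 1 library gave 1577 to 3749 genes higher and 1466 to 3484 lower with knockdown, the lowest without knockdown replicate 2, where the lone library is assumed to vary like the other groups. The ranges were 3142 to 3974 and 2964 to 3874 with overexpression, 3063 to 4607 and 3013 to 4541 in the direct contrast, and 2039 to 3238 and 2028 to 3381 for the mean. MOV10 ranged from 5.04 to 5.18 with overexpression and from -0.68 to -0.54 with knockdown, and 12 to 14 and 10 to 12 lists passed.

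Replicate numbers gave no sign of pairing the libraries: deviations of same-numbered libraries correlated by -0.0847 to 0.0900, others by -0.0900 to 0.0988. Deviations were taken from the group mean, so those of the knockdown libraries mirror each other and the ranges are partly forced. With the replicate number as a block 3649 genes were higher and 3468 lower with overexpression, 2612 and 2557 with knockdown, and MOV10 stood at 5.10 and -0.61. With the block 1 list call was lost. A difference of 1.2-fold was recovered for 43.3% of simulated genes with overexpression and 32.8% with knockdown. The adjustment sets a less strict threshold in the real data, so the share of such changes missed there is not known.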

Other observations

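The tests of 3' UTR words and of the histone genes, and the families of genes defined by their symbols, were chosen only after those results had been seen; the tests of zinc finger genes were added after the zinc finger list had passed but before their own results, and those of other splits before theirs, except that the adjustment of lists in the splits was changed after an initial run. With overexpression, 23 of 262 symbol families passed camera at an adjusted p of 0.05, and 0 with an estimated correlation (adjusted p = 0.717). Among them 21 of 31 POLR genes, which encode RNA polymerase subunits, fell and 4 rose (median -0.21, adjusted p = 0.00261), and 27 of 49 MRPL genes of the mitochondrial ribosome fell and 2 rose (median -0.15, adjusted p = 0.00477). Of 34 collagen genes named COL, 21 rose and 2 fell (median 0.46, adjusted p = 0.000296), and of 12 integrin alpha genes named ITGA, 9 rose and 1 fell (median 0.49, adjusted p = 0.00477). With knockdown 1 family passed, the histone genes, and 0 with an estimated correlation (adjusted p = 0.935).

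Lists that missed the camera threshold are given as counts of genes called higher and lower, with the camera adjusted p. Cholesterol genes stood at 9 and 5 of 32 with overexpression (9 and 5 adjusted over the list alone, adjusted p = 0.186), with INSIG1 at 1.27 ± 0.07 and HMGCS1 at 0.94 ± 0.05, and at 8 and 3 with knockdown (8 and 3 adjusted over the list alone, 0.713). For the lists that follow the counts adjusted over the list alone differed by at most 4 genes. Hypoxia and glycolysis genes stood at 7 and 11 of 30 (0.538) and at 10 and 6 (0.267), with SLC2A3, which holds an 8-base word described below, at -1.14 ± 0.10 with knockdown. The hypoxia list passed with knockdown without knockdown replicate 2, which leaves 1 knockdown library. It also passed without genes holding a 7-base core of the words described below (camera adjusted p = 0.0287), which left 17 of the 30 genes. Since those words were chosen on genes lower with knockdown, that removal favours a higher list by construction. Polycomb genes stood at 5 and 8 of 26 (0.421) and at 7 and 6 (0.627), and retroelement restriction factors at 8 and 7 of 23 (0.598) and at 4 and 2 (0.715). Nuclear genes of oxidative phosphorylation stood at 1 and 15 of 44 with overexpression (0.109), and passed without control replicate 2 (0.0324). With knockdown they stood at 12 and 3 (0.2). With overexpression decapping and P-body factors stood at 7 and 12 of 33 (0.927), interferon-stimulated genes at 9 and 2 of 37 (0.421), ribosomal protein genes at 17 and 8 of 76 (0.576) and neuronal genes at 13 and 13 of 39 (0.624). With knockdown nonsense-mediated decay factors stood at 8 and 1 of 16 (0.123), proteasome genes at 5 and 3 of 31 (0.497), splicing factors at 12 and 3 of 33 (0.268), translation factors at 12 and 4 of 35 (0.576), proliferation genes at 8 and 10 of 45 (0.497), amino acid response genes at 10 and 10 of 38 (0.927) and small nucleolar RNA hosts at 3 and 4 of 17 (0.695). Other helicases of MOV10's superfamily stood at 1 and 3 of 8 (0.693) and at 3 and 0 (0.155). Of markers of other cell types, fibroblast genes stood at 4 and 0 of 6 with overexpression (0.126) and at 1 and 1 with knockdown (0.768), leukocyte genes at 1 and 0 of 5 (0.497) and at 2 and 1 (0.823), and endothelial genes at 0 and 1 of 3 (0.803) and at 0 and 0 (0.574). Across 13637 genes, which are not independent, the Spearman correlation of the log2 fold change with 3' UTR GC content was -0.166 with overexpression and -0.0327 with knockdown, and with 3' UTR length 0.043 and -0.0617. In the scan of 7-base 3' UTR words, genes with CACATCA (z 5.19), AGCCTTA (4.94) and ACATCAA (4.86) were higher with overexpression, beyond the highest absolute z of 4.76 in 100 permutations. With knockdown AGCCTTA and ACATCAA were the highest of all words (4.94 and 4.84), short of the permuted 5.06, and CACATCA stood at 3.18. The permutations shuffle genes, which are not independent, and do not measure the spread between libraries. A z just beyond their highest value is therefore weak evidence. Both comparisons share the control libraries, given an irrelevant siRNA, so the ranks of a word in them are not independent. Why these words rank high in both comparisons was not tested.

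Genes with certain 7-base words in the 3' UTR were lower with knockdown: of 16348 words, GCAAACA (z -11.8), AGCAAAC (-10.4), GTCTGTT (-8.93), TGCAAAC (-6.56) and GGGTCTT (-6.29) lay beyond the highest absolute z of 5.06 in 100 permutations, and 3 leading words were kept by leaving out AGCAAAC and TGCAAAC, which overlap GCAAACA. Base composition is argued against, since the lowest z was -2.38 among 91 words with the bases of GCAAACA in another order and no run of 5 bases shared with it, and so is an effect of the amount of MOV10 that turns with its direction, since genes with the 8-base site AGCAAACA shifted by -0.132 ± 0.0128 with knockdown and by 0.00926 ± 0.0113 with overexpression (mean log2 difference, SE, 597 genes). Seed matches of the MOV10 siRNA remain a candidate explanation: genes with AGCAAACA lay lower than genes with only its 6-base core (difference -0.126 over the genes it was chosen on, and -0.137 ± 0.0216 and -0.114 ± 0.0238, SE, in 5778 and 5777 genes not used to choose it). Genes with only the first or only the last 7 bases of a site did not always lie between. For AGCAAACA they did over all scanned genes (first -0.036 ± 0.0115, last -0.0568 ± 0.0109, core -0.00653 ± 0.00966). They also did in the 5778 genes (-0.0664 ± 0.0171, -0.0524 ± 0.0158 and 0.0066 ± 0.0128). In the 5777 genes the first lay at -0.00771 ± 0.0154 and the last at -0.061 ± 0.0152, against -0.0206 ± 0.0146 for the core. For GTCTGTTA the first lay at -0.045 ± 0.00897 and the last at 0.0162 ± 0.00759, against 0.0151 ± 0.00501. For TGGGTCTT both lay between (-0.0159 ± 0.00984 and -0.0408 ± 0.0113, core -0.00207 ± 0.00749). The permutations and these SEs run over genes, which are not independent, and do not measure the spread between libraries. Of the 5 words all but TGCAAAC occur in the MOV10 mRNA, as do 19.7% of all 7-base words, but only 2 of the 3 8-base sites do, TGGGTCTT being absent, against 5.76% of all 8-base words, and neither the siRNA sequence nor an effect of MOV10 loss without a counterpart on gain was tested.

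Replication-dependent histone genes were higher in both comparisons with control, 22 of them called in both. More RNA without a poly(A) tail in both treated groups is argued against only as far as small RNAs stand for such RNA. The 110 small nucleolar and Cajal body RNAs had a median of 0.0237 ± 0.026 with knockdown, against 0.98 for the histone genes. With overexpression their median was 0.189 ± 0.0377, against 0.96. Whether their counts track histone transcripts without a tail was not tested. Fewer dividing cells would by themselves lower transcripts made in S phase, and a rise would need another route, such as polyadenylated histone transcripts, that was not tested. The median of the proliferation genes was -0.0086 with knockdown over members that went both ways, which decides nothing. A property of the control libraries may also account for it: histone genes differed by a median of -0.0398 between the treated groups, no other untreated library was analysed here, and an effect of either change of MOV10 on histone transcripts stays open and untested.

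Zinc finger genes named ZNF were higher with overexpression (median 0.155, camera adjusted p = 0.000253, adjusted p = 0.382 with an estimated correlation). Offsets for GC content and length left a median of 0.144 (adjusted p = 0.000766), and thinning all libraries to the shallowest left 0.153, which argues against gene composition and depth as the whole cause. An effect of MOV10, of plasmid delivery or of the irrelevant siRNA in the control cells may remain, as hypotheses that the missing plasmid control leaves open. The list was also higher with knockdown, where siRNA was given (median 0.0709, camera adjusted p = 0.0272, adjusted p = 0.549 with an estimated correlation). Plasmid delivery would not account for that rise, and a property of the shared control libraries stays open. Between overexpression and knockdown the list did not pass (median 0.0745, camera adjusted p = 0.227). Reads shared between related ZNF genes were not tested.

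The 6 overexpression and control libraries make 10 splits of 3 against 3, the real one included, too few for a share under 0.05. In 1 of the 10, the real split, 7508 genes were called, and the highest of the others was 0. Every other split mixes overexpression and control libraries, so the treatment difference widens the spread within its groups. Few or no calls there are therefore largely forced and are no support for the real split. The real split passed 14 lists and the highest other 11 (1 of 10 as large), and it passed 23 symbol families and the highest other 9 (1 of 10 as large). For microRNA seed families those not expected in kidney cells included, the real split passed 0, the highest other passed 12, and all 10 splits passed as many as the real one or more. The splits that set overexpression replicates 1 and 3 apart from replicate 2 passed 9 to 12 families, which points to a structure among the overexpression libraries.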
